A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

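Transcript levels of budding yeast were measured on 26 Affymetrix YG_S98 arrays, 2 for each of 13 groups. The deposited table holds processed log2 signals for 9335 probe sets, and the method that made them is not stated. The base of the logarithm is inferred from the values, which lie between 2.09 and 15.1. Array medians lay between 6.64 and 7.00 and the arrays did not share exact quantiles. For 16 arrays, per the file headers, an instrument text file of another kind ("other" unit) gives fluidics and scanner settings and no expression values. Its scan day was used as an array batch in an alternative fit and in medians within scan days. Scan day was not a term of the main model. In the first set of 16 arrays, replicate 1 of 7 groups was scanned on day 1 and replicate 2 of the same groups on day 2, with 7 arrays on each day. Both YPD arrays were scanned on day 3 with no other group, so for YPD the group and the day cannot be separated. For the second set of 10 arrays no scan day was at hand.

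Groups were taken from the sample labels. Columns were matched to labels by sample identifier, and all columns had a label. Values were quantile normalized between arrays. The 60 control probe sets were left out, as were 1399 whose highest group mean did not exceed the 25th percentile of all values (log2 5.44), which left 7876 probe sets. Gene names came from the supplied probe annotation and were brought up to date with the supplied assembly table, used for names only. Of all probe sets, 6504 had 1 gene, 328 had several and 2443 had none listed. Probe sets with several genes or none were tested but not named. The tested set held 6133 probe sets with 1 gene, for 5464 genes, and a gene with several probe sets was given by the probe set with the highest mean. Among 275 genes with several probe sets, opposite calls occurred for 5 under benomyl at 1 h and for 1 at 10 °C at 4 h, and none of these was a named gene. Probe set names ending in s_at, f_at or i_at mark probes that can match near-identical copies, and such genes are named as uncertain.

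Each comparison was a contrast in a limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 13 groups, fitted to all 26 arrays with an intensity trend in the variance. The fit left 13 residual degrees of freedom and the median prior had 5.24. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05, with the count of at least 2-fold beside it. Log2 fold changes are given with the model's standard error and n = 2 arrays per group. Differences between effects (benomyl at 4 h against 1 h, cold at 4 h against 1 h, and benomyl against cold at each time) were tested as contrasts of contrasts. The replicate numbers did not pair the samples: across probe sets, the correlation of residuals between groups ran from -0.155 to 0.309 in the first set and from -0.289 to 0.391 in the second. Replicate number was therefore not a term of the model.

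The main comparisons, test, filter, 27 gene lists and naming rule were chosen before the data were examined. The rule names the 10 largest rises and falls among called genes whose arrays do not overlap between groups (3 each way in comparisons other than benomyl and cold against their controls). It adds up to 4 members of each list with the smallest adjusted p, and 11 genes named whatever their values. These are TUB1, TUB2, TUB3, IME1, IME2, NDT80, CLB1, SPS1, FLR1, PDR5 and MAD2. The lists cover meiotic entry regulators, recombination and synapsis, meiotic division regulators, prospore membrane, spore wall, DNA replication, DNA damage, histones, the mitotic cell cycle, tubulins and their folding, microtubule motors and associated proteins, and the spindle checkpoint. They also cover multidrug resistance, targets of the oxidative stress factor Yap1, heat shock chaperones, general stress, cell wall integrity, cold-induced genes, ribosomal proteins, ribosome biogenesis, the proteasome, the glyoxylate cycle and gluconeogenesis, glycolysis and glucose uptake, the TCA cycle and respiration, amino acid biosynthesis, sulfur and methionine, and haploid mating markers. Counts cover the measured members of each list. Lists with at least 4 measured genes (26 of the 27) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation, and fry, were run beside it. Member counts are given over all probe sets and adjusted over the list alone. Genes of the undrugged course were those called higher by at least 2-fold from 1 h to 4 h. For benomyl they were chosen on the second set and for cold on the DMSO arrays, so that choice and test shared no array.

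Alternatives changed 1 choice at a time: values as deposited, median centring, no filter or a stricter filter, no variance trend, only the groups of the contrast, replicate number or scan day as a block, another control group, another set test and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Array weights, a fit without the benomyl 1 h arrays and the second-set 1 h controls, and a few others were added after the data had been seen. The model was tested on simulated data with known changes. In each run 198 to 200 probe sets were changed, by 0.5, 1 or 2, and the false share of calls depends on that number. With equal spread in all groups, 0.0259% to 0.182% of unchanged probe sets were called. With each group's own spread these were 2.11% (162, beside 141 recovered changes) under benomyl at 1 h and 0.842% (65, beside 140) at 10 °C at 1 h, since the benomyl 1 h and second-set 1 h control arrays varied 1.82 and 1.53 times as much as the pooled spread. At 4 h they were 0.0259% for benomyl and 0.0518% for cold. None of 19 unchanged simulated lists was called in any of these runs. The simulated noise was drawn independently for each probe set, so these runs cannot test lists whose genes vary together. Arrays give no counts, so the number of arrays limits the precision.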

Results

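Budding yeast cells were taken from rich glucose medium (YPD) through acetate medium (YPA) overnight into sporulation medium, and 4 h later they were filtered and resuspended. The samples compare cells given benomyl, a drug that depolymerizes microtubules, in the solvent dimethyl sulfoxide (DMSO) with cells given DMSO alone, 1 h and 4 h after resuspension. A second set compares cells moved to 10 °C with cells of the same age whose label gives no temperature after filtration. It is taken here, and in the figures, as room temperature, which is an assumption. The only temperature their labels give is 30 °C, for the growth before. The cold medium held DMSO and, per the labels, its controls were not described as holding any. Values are log2 fold changes ± standard error, n = 2 arrays per group, unless stated. The p-values measure spread between arrays, which may be technical, because the labels do not say that arrays come from separate cultures. With 2 arrays per group the precision of each value is limited. A gene is said to have risen or fallen only where its limma adjusted p passed the threshold, and counts over the list alone adjust p over that list.

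In acetate medium compared with glucose medium, FIT1, a cell wall mannoprotein that retains iron, rose (3.83 ± 0.39), as did TIS11, which binds mRNAs in iron starvation (3.48 ± 0.66), and the siderophore transporter SIT1 (3.46 ± 0.29). OPT1, an oligopeptide transporter (-2.92 ± 0.25), THI2, an activator of thiamine genes (-2.87 ± 0.18), and FRE7 (-2.75 ± 0.16) fell most. IME1, the inducer of meiotic entry, rose (1.96 ± 0.29). Among heat shock chaperones 15 of 17 rose, 15 over the list alone, median 1.09, limma camera adjusted p = 2.04e-12 and 0.00104 with an estimated correlation. Multidrug resistance genes were lower: 8 of 11 fell, 9 over the list alone, median -1.29, limma camera adjusted p = 8.9e-06 and 0.0296 with an estimated correlation. Proteasome genes were higher: 24 of 32 rose, 28 over the list alone, median 0.56, limma camera adjusted p = 1.83e-11 and 0.303 with an estimated correlation. In total 1234 probe sets were higher and 1391 lower (247 and 267 by at least 2-fold), and 1486 and 1242 with median centring. Both YPD arrays were scanned on a day of their own, so the medium and the scan day cannot be told apart, and without replicate 2 of YPA 1696 probe sets were called.

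After 4 h in sporulation medium, meiotic recombination genes stood far above their level in acetate. ECM11, of the synaptonemal complex (4.95 ± 0.14), the chromosome axis gene HOP1 (4.87 ± 0.17) and the recombinase DMC1 (4.73 ± 0.21) rose most. YRO2 (-4.97 ± 0.29), SNR6, the U6 small nuclear RNA (-3.83 ± 0.19), and the glucose transporter gene HXT6 (-3.75 ± 0.18, uncertain, since its probes can match near-identical copies) fell most. The meiotic entry genes IME1 (1.42 ± 0.29) and IME2 (3.83 ± 0.42) rose, as did the alpha-tubulin genes TUB1 (2.63 ± 0.13) and TUB3 (2.01 ± 0.13) and the beta-tubulin gene TUB2 (1.73 ± 0.10). Of recombination and synapsis genes 24 of 24 rose, 24 over the list alone, median 3.45, limma camera adjusted p = 2.72e-13 and 0.203 with an estimated correlation. DNA replication genes were higher (23 of 26 rose, 23 over the list alone, median 0.95, limma camera adjusted p = 3.2e-07 and 0.348 with an estimated correlation). Microtubule motors and associated proteins were higher too (15 of 16 rose, 15 over the list alone, median 0.96, limma camera adjusted p = 0.000157 and 0.203 with an estimated correlation). Among meiotic entry regulators 8 of 10 rose, 8 over the list alone, median 1.23, limma camera adjusted p = 0.015 and 0.425 with an estimated correlation. Sulfur and methionine genes were higher (13 of 14 rose and 1 fell, 13 and 1 over the list alone, median 1.72, limma camera adjusted p = 4.55e-05 and 0.38 with an estimated correlation). Glycolysis genes were lower (15 of 16 fell, 15 over the list alone, median -0.57, limma camera adjusted p = 0.00143 and 0.38 with an estimated correlation). Ribosomal protein genes were lower too (1 of 80 rose and 56 fell, 1 and 56 over the list alone, median -0.61, limma camera adjusted p = 3.43e-08 and 0.425 with an estimated correlation). The numbers of probe sets higher and lower were 2248 and 2326 (953 and 785 by at least 2-fold). With median centring the median of all probe sets moved to -0.15 and the split was 1988 and 2821. With values as deposited the split was 2581 and 1990.

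Spore-forming genes were higher 1 h after filtration and resuspension without DMSO than before it, a comparison that also spans 1 h of sporulation. SPR2 (4.17 ± 0.33), RRT5 (3.85 ± 0.25) and SPS2 (3.78 ± 0.34) rose most, and the B-type cyclin gene CLB1 (1.57 ± 0.32) and the sporulation kinase gene SPS1 (2.66 ± 0.27) rose too. RTC3 (-1.51 ± 0.34), CTS1 (-1.27 ± 0.28) and NDJ1 (-1.20 ± 0.30) fell most. Of prospore membrane genes 13 of 16 rose, 13 over the list alone, median 1.97, limma camera adjusted p = 7.1e-29 and 0.00847 with an estimated correlation, with medians within scan days 1 and 2 of 1.86 and 1.87. Of spore wall genes 13 of 19 rose, 14 over the list alone, median 2.00, limma camera adjusted p = 4.99e-28 and 0.00725 with an estimated correlation, with medians within the scan days of 1.94 and 1.94. Meiotic division regulators were higher: 5 of 14 rose, 8 over the list alone, median 0.59, limma camera adjusted p = 2.53e-11 and 0.0876 with an estimated correlation. In all 170 probe sets were higher and 73 lower (111 and 13 by at least 2-fold), and with values as deposited the split was 185 and 23. In the second set the same comparison, outside the main ones, gave 54 higher and 133 lower. Prospore membrane genes had a median of 0.30 (2 of 16 higher) and spore wall genes 0.20 (2 of 19). Fewer were called in the first set without filtered replicate 1 (143) or 2 (131) or without replicate 2 of the 4 h sporulation group (124), and more with array weights (804) or only the groups of the contrast (507).

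In DMSO for 1 h, against no DMSO, CIN5, a bZIP transcription factor gene (3.73 ± 0.30), FMP48 (2.03 ± 0.33) and ISF1 (2.02 ± 0.28) rose most, and the mitochondrial aldehyde dehydrogenase gene ALD5 (-1.05 ± 0.23), MET17 (-0.95 ± 0.21) and INA1 (-0.92 ± 0.17) fell most. Of general stress genes 3 of 23 rose, 6 over the list alone, median 0.46, limma camera adjusted p = 1.94e-10 and 0.205 with an estimated correlation, and medians within scan days 1 and 2 were 0.70 and 0.29. Of sulfur and methionine genes 1 of 14 fell, 3 over the list alone, median -0.67, limma camera adjusted p = 7.66e-07 and 0.328 with an estimated correlation, and medians within the scan days were -0.93 and -0.32. Prospore membrane genes had no member called (median -0.30, limma camera adjusted p = 0.00212 and 0.65 with an estimated correlation). Their medians turned sign between scan days 1 and 2 (0.10 and -0.81), as did those of spore wall (0.12 and -0.65) and division genes (0.08 and -0.58). In all 28 probe sets were higher and 17 lower (19 and 1 by at least 2-fold), and without filtered replicate 1 or 2 the count was 10 or 15. It was 288 with array weights, 213 in the fit without the benomyl 1 h and second-set 1 h control arrays, and 24 with the replicate number as a block. Without replicate 1 of DMSO the balance turned, with 9 higher and 40 lower.

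Between 1 h and 4 h in DMSO the genes of meiotic division and spore formation rose together. SRD1 (5.86 ± 0.25), GAT4, a GATA zinc finger gene (5.17 ± 0.18), and SGA1 (4.76 ± 0.25) rose most, and ISF1 (-2.98 ± 0.28), CIN5 (-2.73 ± 0.30) and RGI1 (-2.66 ± 0.20) fell most. NDT80, the transcription factor gene of mid-sporulation, rose (1.88 ± 0.31), as did CLB1 (3.45 ± 0.32) and SPS1 (3.84 ± 0.27). Of meiotic division regulators 13 of 14 rose, 13 over the list alone, median 1.89, limma camera adjusted p = 1.07e-09 and 0.142 with an estimated correlation. Among prospore membrane genes 15 of 16 rose, 15 over the list alone, median 2.36, limma camera adjusted p = 1.61e-11 and 0.142 with an estimated correlation. Spore wall genes followed: 18 of 19 rose and 1 fell, 18 and 1 over the list alone, median 2.54, limma camera adjusted p = 4.83e-12 and 0.142 with an estimated correlation. Within scan days 1 and 2 the medians were 1.81 and 2.996 for prospore membrane genes and 2.00 and 3.01 for spore wall genes. Ribosomal protein genes were lower: 3 of 80 rose and 68 fell, 3 and 69 over the list alone, median -0.71, limma camera adjusted p = 9.21e-09 and 0.615 with an estimated correlation. In all 1399 probe sets were higher and 2035 lower (738 and 214 by at least 2-fold). The median of all probe sets stood at -0.15, and with values as deposited the split was 1702 and 1200.

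The second set repeated this course without DMSO stated. SPR2 (5.70 ± 0.33), YPR078C (5.42 ± 0.34) and RRT5 (5.21 ± 0.25) rose most, and CHA1 (-1.77 ± 0.28), PIR1 (-1.64 ± 0.25) and NCE103 (-1.44 ± 0.27) fell most. Of meiotic division regulators 11 of 14 rose, 13 over the list alone, median 1.48, limma camera adjusted p = 1.3e-16 and 0.0242 with an estimated correlation. Of prospore membrane genes 13 of 16 rose, 15 over the list alone, median 2.59, limma camera adjusted p = 1.27e-27 and 0.0103 with an estimated correlation. Spore wall genes moved further: 14 of 19 rose, 15 over the list alone, median 3.60, limma camera adjusted p = 1.27e-27 and 0.00774 with an estimated correlation. Across genes the changes of both courses correlated (Pearson r = 0.740 over 5464 genes, which are not independent replicates). In all 431 probe sets were higher and 207 lower (219 and 27 by at least 2-fold), against 536 and 58 with values as deposited and 423 and 122 with median centring. With array weights 351 were called. Without replicate 2 of the 1 h group 1044 were called, and without replicate 1 or 2 of the 4 h group 405 or 306.

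The sets differed between groups with like labels. In the second set, 1 h after filtration, SPR2 (-4.54 ± 0.33), LDS2 (-4.18 ± 0.40) and LDS1 (-4.04 ± 0.22) were lowest against the first set. RDN5-1 (2.76 ± 0.45) and RDN5-3 (1.88 ± 0.24), 5S ribosomal RNA genes whose probes can match near-identical copies, and RTC3 (1.79 ± 0.34) were highest. Among prospore membrane genes 16 of 16 fell, 16 over the list alone, median -2.21, limma camera adjusted p = 5.63e-17 and 0.0702 with an estimated correlation. Of spore wall genes 1 of 19 rose and 14 fell, 1 and 14 over the list alone, median -2.37, limma camera adjusted p = 3.58e-13 and 0.0702 with an estimated correlation. General stress genes were higher: 11 of 23 rose, 12 over the list alone, median 0.57, limma camera adjusted p = 8.41e-05 and 0.748 with an estimated correlation. In all 853 probe sets were higher and 920 lower (170 and 168 by at least 2-fold). With the replicate number as a block 1099 were called, with array weights 711 and with only the groups of the contrast 279. With values as deposited the split was 512 and 1737 and the median of all probe sets -0.19, and with median centring the split was 920 and 857. The count was 690 without replicate 1 of the first set, 801 without its replicate 2, and 548 without replicate 1 of the second. Before filtration, 4 h into sporulation, an unplanned comparison gave 920 probe sets higher in the second set and 1065 lower. There the first set's label was shorter and gave no acetate content. At 4 h after filtration, also outside the main ones, 1706 were higher and 1526 lower than in DMSO. Medians were -1.22 for division, -1.56 for prospore membrane and -1.51 for spore wall genes (camera adjusted p = 0.377 with an estimated correlation for each). These undrugged groups, which differ in set and in the DMSO stated, lay as far apart in those lists as benomyl and DMSO at 4 h (-1.24, -1.16 and -1.16).

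Benomyl for 1 h raised genes of drug efflux and redox defence above the DMSO control. The largest rises were in YKL070W (6.58 ± 0.20), the NADPH oxidoreductase gene OYE3 (6.06 ± 0.26), FRM2, of the nitroreductase family (5.71 ± 0.17), YLR460C (5.52 ± 0.32) and the methylglyoxal reductase gene GRE2 (5.45 ± 0.24). Next were YLL056C (5.08 ± 0.31), the plasma membrane transporter genes AZR1 (4.95 ± 0.33), FLR1 (4.92 ± 0.36) and YHK8 (4.81 ± 0.24), and the aryl-alcohol dehydrogenase gene AAD4 (4.77 ± 0.17, uncertain, since its probes can match near-identical copies). The ammonium permease gene MEP2 (-4.53 ± 0.27), the glutamate dehydrogenase gene GDH1 (-4.31 ± 0.17), the steryl ester hydrolase gene YEH1 (-4.02 ± 0.24), the allantoin permease gene DAL4 (-3.83 ± 0.33) and the amino acid permease gene AGP1 (-3.61 ± 0.16) fell most. RPL6B (-3.44 ± 0.19), the sterol isomerase gene ERG2 (-3.44 ± 0.21), HTB2, for histone H2B (-3.34 ± 0.27), the spore wall chitin deacetylase gene CDA2 (-3.33 ± 0.23) and the cytochrome b5 gene CYB5 (-3.28 ± 0.30) followed. In all 2016 probe sets were higher and 2107 lower (684 and 858 by at least 2-fold), against 1655 and 2436 with values as deposited and 2239 and 1946 with median centring. The benomyl 1 h arrays differed more than other pairs (standard deviation 0.44, Pearson r = 0.942 across probe sets), the pooled spread understates this, and with array weights 2019 probe sets were called and with only the groups of the contrast 1208. On simulated data with this spread and 200 changed probe sets, 141 changes were recovered and 162 of 7678 unchanged probe sets were called, a share that cannot be carried over to the counts here.

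At 1 h under benomyl no tubulin gene was higher. TUB2 (-0.81 ± 0.10) and TUB3 (-1.52 ± 0.13) fell, and TUB1 had -0.17 ± 0.13 (limma adjusted p = 0.295). IME1 (-1.68 ± 0.29), IME2 (-2.89 ± 0.42), CLB1 (-1.73 ± 0.32), NDT80 (-1.29 ± 0.31) and SPS1 (-1.01 ± 0.27) fell, while the ABC transporter gene PDR5 (2.88 ± 0.19, uncertain for its probes) and the spindle checkpoint gene MAD2 (0.43 ± 0.16) rose. The calls of NDT80, SPS1 and MAD2 ended with array weights, and those of IME1, IME2 and CLB1 ended with only the groups of the contrast. Single arrays carried part of these sizes. Without replicate 1 of DMSO SPS1 stood at -0.33, NDT80 at -0.80 (neither called) and CLB1 at -1.002, and without replicate 2 of benomyl IME1 stood at -0.90 and IME2 at -1.80. Of tubulins and folding genes 1 of 15 rose and 7 fell, 1 and 7 over the list alone, median -0.38, limma camera adjusted p = 0.047 and 0.201 with an estimated correlation. TUB4 (-1.20 ± 0.12) and PAC10 (-1.40 ± 0.16) fell too, and the list's call ended with median centring, values as deposited, only the groups of the contrast or the control without DMSO, and without replicate 1 of benomyl or replicate 2 of DMSO. Of microtubule motors and associated genes 1 of 16 rose and 9 fell, 1 and 9 over the list alone, median -0.41, limma camera adjusted p = 0.106 and 0.412 with an estimated correlation. Called members included STU1 (-1.79 ± 0.20), ASE1 (2.09 ± 0.28), STU2 (-0.96 ± 0.20) and NDC80 (-1.25 ± 0.31). Of spindle checkpoint genes 1 of 9 rose and 4 fell, 1 and 6 over the list alone, median -0.55, limma camera adjusted p = 0.19 and 0.505 with an estimated correlation. Called members included IPL1 (-1.52 ± 0.28), BUB2 (-0.79 ± 0.16), MAD3 (-0.55 ± 0.16) and ESP1 (-0.71 ± 0.26).

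Defence lists were higher at 1 h of benomyl. Multidrug resistance genes, Yap1 targets and chaperones were the only lists fixed before the data were examined, among those called for benomyl or cold against its control, that held with an estimated correlation between genes. Of multidrug resistance genes 10 of 11 rose, 10 over the list alone, median 2.13, limma camera adjusted p = 2.92e-08 and 0.00809 with an estimated correlation. Its members included SNQ2 (3.24 ± 0.15), PDR10 (2.59 ± 0.15) and TPO1 (2.26 ± 0.16), with medians within scan days 1 and 2 of 1.98 and 2.09. Of targets of the oxidative stress factor Yap1 14 of 17 rose, 14 over the list alone, median 2.75, limma camera adjusted p = 1.33e-11 and 0.00809 with an estimated correlation. Named members were GLR1 (3.17 ± 0.11) and TRR1 (2.97 ± 0.12), with medians within the scan days of 2.19 and 3.05. Of heat shock chaperones 12 of 17 rose, 12 over the list alone, median 0.78, limma camera adjusted p = 5.95e-05 and 0.0344 with an estimated correlation. The list held HSP30 (3.66 ± 0.21), CPR6 (1.63 ± 0.12), AHA1 (1.40 ± 0.12) and SSA3 (2.09 ± 0.21), with medians within the scan days of 0.70 and 1.10. General stress genes were higher (13 of 23 rose, 13 over the list alone, median 0.65, limma camera adjusted p = 0.000436 and 0.314 with an estimated correlation), among them SPI1 (2.72 ± 0.20), TSL1 (1.64 ± 0.15), GSY2 (2.02 ± 0.18) and YGP1 (1.23 ± 0.16). Proteasome genes were higher (25 of 32 rose, 25 over the list alone, median 0.75, limma camera adjusted p = 2.31e-08 and 0.251 with an estimated correlation), led by their regulator RPN4 (2.03 ± 0.16) with PRE8 (1.02 ± 0.13), RPN12 (1.12 ± 0.15) and PRE7 (0.99 ± 0.14). Sulfur and methionine genes were higher (11 of 14 rose, 11 over the list alone, median 1.59, limma camera adjusted p = 1.87e-05 and 0.259 with an estimated correlation), among them MET2 (2.31 ± 0.20), SUL2 (2.36 ± 0.26), CYS3 (2.67 ± 0.29) and MET17 (1.64 ± 0.21). DNA damage genes were higher (5 of 8 rose, 5 over the list alone, median 1.25, limma camera adjusted p = 0.00177 and 0.168 with an estimated correlation): RNR3 (3.15 ± 0.14, uncertain for its probes), RAD54 (1.30 ± 0.12), MAG1 (1.67 ± 0.18) and RNR2 (1.69 ± 0.20). Within scan days 1 and 2 the medians were 0.71 and 0.71 for general stress, 0.89 and 0.63 for the proteasome, 1.33 and 1.77 for sulfur and 1.31 and 1.19 for DNA damage genes.

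Sporulation and growth lists were lower at 1 h of benomyl. Of recombination and synapsis genes 21 of 24 fell, 21 over the list alone, median -1.72, limma camera adjusted p = 4.05e-06 and 0.251 with an estimated correlation. Among them were MSH5 (-1.64 ± 0.18), REC8 (-1.70 ± 0.19), SPO22 (-1.88 ± 0.23) and DMC1 (-1.57 ± 0.21). Of meiotic division regulators 12 of 14 fell, 12 over the list alone, median -1.34, limma camera adjusted p = 0.000176 and 0.259 with an estimated correlation. Its members included MAM1 (-1.85 ± 0.16), SGO1 (-2.06 ± 0.19), CDC5 (-2.71 ± 0.30) and CLB4 (-1.38 ± 0.21). Of prospore membrane genes 15 of 16 fell, 15 over the list alone, median -1.31, limma camera adjusted p = 5.95e-05 and 0.259 with an estimated correlation. Named members were SPO77 (-2.20 ± 0.26), SPR3 (-2.80 ± 0.34), SPO75 (-1.69 ± 0.23) and DON1 (-1.83 ± 0.25). Of spore wall genes 2 of 19 rose and 13 fell, 2 and 15 over the list alone, median -1.33, limma camera adjusted p = 0.00293 and 0.314 with an estimated correlation (CDA1 -2.84 ± 0.31, SPS4 -2.47 ± 0.29, SPS100 1.88 ± 0.16). Of DNA replication genes 1 of 26 rose and 17 fell, 1 and 17 over the list alone, median -0.67, limma camera adjusted p = 0.000216 and 0.259 with an estimated correlation. The list held POL2 (-1.63 ± 0.13), PRI2 (-1.40 ± 0.15) and MCM7 (-1.08 ± 0.15). Within scan days 1 and 2 the medians were -1.03 and -2.21 for recombination, -1.45 and -1.01 for division, -1.82 and -1.30 for prospore membrane, -1.89 and -0.72 for spore wall and -0.53 and -0.99 for replication genes. Without replicate 1 of DMSO the spore wall list stood at -0.72 and the division list at -0.86, and without replicate 2 of benomyl the recombination list stood at -1.05, all still called. Both measured histone genes fell, HTB2 and HTB1 (-0.37 ± 0.10), too few for a test.

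Ribosomal protein genes fell nearly as a whole at 1 h of benomyl: 1 of 80 rose and 77 fell, 1 and 77 over the list alone, median -1.93, limma camera adjusted p = 4.12e-30 and 0.122 with an estimated correlation, with medians within scan days 1 and 2 of -1.80 and -2.08. RPL22A (-3.26 ± 0.18) was among them. Ribosome biogenesis genes were lower (2 of 45 rose and 26 fell, 2 and 27 over the list alone, median -0.72, limma camera adjusted p = 0.000123 and 0.412 with an estimated correlation), with SSF1 (-2.05 ± 0.18), NOP56 (-2.14 ± 0.19), RRP1 (-1.87 ± 0.17) and RPA135 (-1.56 ± 0.15). Of TCA cycle and respiration genes 15 of 30 fell, 15 over the list alone, median -0.33, limma camera adjusted p = 0.00209 and 0.281 with an estimated correlation. Among them were FUM1 (-2.07 ± 0.16), LSC1 (-1.02 ± 0.13), ACO1 (-1.64 ± 0.20) and COX5A (-1.10 ± 0.15), and the call ended with median centring and with the control without DMSO. Of amino acid biosynthesis genes 2 of 24 rose and 17 fell, 2 and 17 over the list alone, median -0.97, limma camera adjusted p = 0.00336 and 0.432 with an estimated correlation. Its members included ARG1 (-3.14 ± 0.20), HIS1 (-2.98 ± 0.20), LYS9 (-2.24 ± 0.18) and ARG4 (-2.98 ± 0.25). Without replicate 1 of benomyl the calls of the ribosome biogenesis and amino acid lists ended. Meiotic entry regulators had no call (1 of 10 rose and 6 fell, 1 and 7 over the list alone, median -0.76, limma camera adjusted p = 0.078 and 0.432 with an estimated correlation). Their medians within scan days 1 and 2 were -0.27 and -1.44, and without replicate 1 of benomyl they stood at -1.32 with a call (limma camera adjusted p = 0.00828). Array weights gave calls to the entry (limma camera adjusted p = 0.0358) and gluconeogenesis lists (0.0233). The mitotic cell cycle list had none (3 of 13 rose and 5 fell, 3 and 5 over the list alone, median -0.35, limma camera adjusted p = 0.512 and 0.722 with an estimated correlation), nor had cell wall integrity (1 of 12 rose and 6 fell, 1 and 6 over the list alone, median -0.37, limma camera adjusted p = 0.143 and 0.432 with an estimated correlation). Cold-induced genes were not called as a list (1 of 11 rose and 5 fell, 1 and 6 over the list alone, median -0.58, limma camera adjusted p = 0.0681 and 0.214 with an estimated correlation), and gained a call with the control without DMSO. The glyoxylate cycle and gluconeogenesis list was not called (6 of 12 fell, 6 over the list alone, median -0.64, limma camera adjusted p = 0.118 and 0.59 with an estimated correlation). Its medians within scan days 1 and 2 were -0.02 and -1.50, and without replicate 1 of benomyl it stood at -1.44 with a call (limma camera adjusted p = 0.000186). Glycolysis and glucose uptake genes were not called as a list (5 of 16 rose and 3 fell, 5 and 3 over the list alone, median 0.21, limma camera adjusted p = 0.106 and 0.432 with an estimated correlation), and gained a call with values as deposited and without replicate 1 of benomyl (0.45, limma camera adjusted p = 0.0274). Haploid mating markers were not called either (3 of 12 rose and 2 fell, 3 and 2 over the list alone, median 0.10, limma camera adjusted p = 0.578 and 0.59 with an estimated correlation).

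Benomyl for 4 h left the later sporulation genes lower while efflux genes stayed higher. The sulfonate dioxygenase gene JLP1 (5.37 ± 0.21), YLL056C (4.38 ± 0.31), the ABC transporter gene SNQ2 (3.64 ± 0.15), the amino acid permease gene AGP3 (2.75 ± 0.20) and GRE2 (2.48 ± 0.24) rose most. The biotin transporter gene VHT1 (2.36 ± 0.27), SNG1 (2.35 ± 0.21), FIT2 (2.29 ± 0.55), YGR035C (2.28 ± 0.20) and YNL134C (2.12 ± 0.27) followed. The hexose transporter gene HXT10 (-3.56 ± 0.17), GAT4 (-3.51 ± 0.18), YNR014W (-3.15 ± 0.39), HMS1 (-3.08 ± 0.20) and the basic amino acid permease gene ALP1 (-2.88 ± 0.23) fell most. The cell wall sensor gene WSC4 (-2.84 ± 0.17), PRM6 (-2.82 ± 0.18), YLR012C (-2.72 ± 0.21), SRD1 (-2.71 ± 0.25) and the decarboxylase gene ARO10 (-2.70 ± 0.17) followed. NDT80 (-1.19 ± 0.31), CLB1 (-1.57 ± 0.32), SPS1 (-1.06 ± 0.27), TUB2 (-0.28 ± 0.10), TUB3 (-0.46 ± 0.13) and IME2 (-1.24 ± 0.42) fell, and FLR1 (1.78 ± 0.36) and PDR5 (1.19 ± 0.19) rose. TUB1 had -0.03 ± 0.13, IME1 0.15 ± 0.29 and MAD2 -0.21 ± 0.16, none of them called. Without replicate 1 of benomyl FLR1 stood at 0.93 and the calls of TUB3, IME2 and NDT80 ended, and that of TUB2 ended with no variance trend. In all 1309 probe sets were higher and 1256 lower (203 and 537 by at least 2-fold), against 851 and 1479 with values as deposited and 1112 and 1390 with median centring. The count was 1626 without replicate 1 of benomyl and 1516 without replicate 2 of DMSO, and 4121 with array weights.

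Of the lists at 4 h of benomyl, none held its call with an estimated correlation. Of meiotic division regulators 13 of 14 fell, 13 over the list alone, median -1.24, limma camera adjusted p = 4.79e-07 and 0.156 with an estimated correlation. Named members were CLB6 (-1.87 ± 0.20), CLB4 (-1.90 ± 0.21), CDC20 (-1.62 ± 0.22) and SGO1 (-1.28 ± 0.19). Among prospore membrane genes 14 of 16 fell, 14 over the list alone, median -1.16, limma camera adjusted p = 4.79e-07 and 0.201 with an estimated correlation. The list held ADY4 (-1.54 ± 0.19), SPO75 (-1.49 ± 0.23), SPO77 (-1.60 ± 0.26) and SMK1 (-1.67 ± 0.28). Of spore wall genes 1 of 19 rose and 16 fell, 1 and 16 over the list alone, median -1.16, limma camera adjusted p = 4.79e-07 and 0.156 with an estimated correlation. Among them were SPS22 (-1.94 ± 0.23), OSW2 (-2.01 ± 0.24), OSW1 (-1.90 ± 0.26) and CRR1 (-1.55 ± 0.24). Of microtubule motors and associated genes 1 of 16 rose and 8 fell, 1 and 9 over the list alone, median -0.58, limma camera adjusted p = 0.000665 and 0.156 with an estimated correlation. Its members included STU2 (-1.94 ± 0.20), SPC42 (-1.65 ± 0.19), SPC110 (-0.79 ± 0.14) and SPC98 (-1.10 ± 0.20). Haploid mating markers were lower (5 of 12 fell, 6 over the list alone, median -0.32, limma camera adjusted p = 0.0216 and 0.156 with an estimated correlation), among them STE5 (-1.30 ± 0.14), STE4 (-1.33 ± 0.19), FAR1 (-1.27 ± 0.18) and STE12 (-0.80 ± 0.16), and the call ended with values as deposited. Within scan days 1 and 2 the medians were -1.36 and -1.10 for division, -1.17 and -1.10 for prospore membrane, -1.04 and -1.31 for spore wall and -0.64 and -0.55 for motor genes.

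Higher lists at 4 h of benomyl were multidrug resistance, Yap1 targets, general stress, sulfur, respiration and amino acid genes. Chaperones (6 of 17 rose and 2 fell, 8 and 2 over the list alone, median 0.38, limma camera adjusted p = 0.262), proteasome genes (3 of 32 rose, 1 over the list alone, median 0.17, limma camera adjusted p = 0.233) and DNA damage genes (median 0.04, limma camera adjusted p = 0.742), called at 1 h, were not called at 4 h. The proteasome list gained a call without replicate 1 of benomyl (0.26, limma camera adjusted p = 0.0243) and turned to -0.03 with values as deposited. Of multidrug resistance genes 8 of 11 rose and 1 fell, 8 and 1 over the list alone, median 0.92, limma camera adjusted p = 0.00398 and 0.156 with an estimated correlation. Named members were TPO1 (1.44 ± 0.16), PDR10 (1.02 ± 0.15) and ICT1 (-1.08 ± 0.16). Of Yap1 targets 12 of 17 rose and 1 fell, 13 and 1 over the list alone, median 0.80, limma camera adjusted p = 9.04e-05 and 0.156 with an estimated correlation. The list held TRX2 (1.10 ± 0.11), GLR1 (0.99 ± 0.11), AHP1 (1.20 ± 0.13) and GTT2 (1.63 ± 0.23). Of general stress genes 12 of 23 rose and 1 fell, 13 and 1 over the list alone, median 0.45, limma camera adjusted p = 0.00969 and 0.555 with an estimated correlation. Among them were YGP1 (2.06 ± 0.16), TFS1 (1.87 ± 0.20), SIP18 (2.11 ± 0.32) and HXK1 (0.87 ± 0.15). Of sulfur and methionine genes 10 of 14 rose, 14 over the list alone, median 1.00, limma camera adjusted p = 4.92e-05 and 0.296 with an estimated correlation. Its members included MET17 (1.70 ± 0.21), MET10 (1.45 ± 0.21), MET3 (1.32 ± 0.20) and CYS3 (1.62 ± 0.29). Of TCA cycle and respiration genes 19 of 30 rose and 1 fell, 20 and 2 over the list alone, median 0.46, limma camera adjusted p = 0.000711 and 0.296 with an estimated correlation. Named members were COX8 (1.25 ± 0.15), COX4 (0.98 ± 0.13), COX6 (1.07 ± 0.15) and QCR2 (1.08 ± 0.16). For amino acid biosynthesis genes 6 of 24 rose and 1 fell, 6 and 1 over the list alone, median 0.56, limma camera adjusted p = 0.0363 and 0.712 with an estimated correlation. The list held HIS4 (1.55 ± 0.25). The calls of the respiration and amino acid lists ended with median centring and with values as deposited. That of the amino acid list also ended with fry, with the stricter dim filter, without replicate 1 of benomyl and without replicate 2 of DMSO. Ribosomal protein genes were lower (2 of 80 rose and 15 fell, 1 and 14 over the list alone, median -0.11, limma camera adjusted p = 0.01 and 0.712 with an estimated correlation), and without replicate 2 of benomyl the list turned to 0.03 with no call. That call also ended with fry and without replicate 1 of DMSO. Recombination and synapsis genes had no call (2 of 24 rose, 2 over the list alone, median 0.39, limma camera adjusted p = 0.111 and 0.712 with an estimated correlation), and the 2 that rose were REC8 (0.72 ± 0.19) and HOP1 (0.62 ± 0.17). That list gained a call with array weights (limma camera adjusted p = 0.0188), in the fit without the benomyl 1 h and second-set 1 h control arrays (0.00883), with only the groups of the contrast (0.00485) and without replicate 1 of benomyl (0.0271). Median, mean and test differed in sign for meiotic entry (0.13, -0.04, down), DNA damage (0.04, -0.05, down), cell wall integrity (-0.10, 0.10, up), ribosome biogenesis (0.05, -0.04, down) and gluconeogenesis (0.10, 0.07, down).

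The benomyl effect changed between 1 h and 4 h. MEP2 (5.30 ± 0.38), the fatty acid synthase gene FAS1 (4.75 ± 0.37, uncertain for its probes) and GDH1 (4.71 ± 0.24) moved up most, and YDL218W (-6.83 ± 0.58), YKL070W (-6.68 ± 0.29) and FRM2 (-5.43 ± 0.23) moved down most. For recombination and synapsis genes the difference was higher in 21 of 24 (22 over the list alone), median 2.11, limma camera adjusted p = 1.77e-06 and 0.239 with an estimated correlation. For ribosomal protein genes it was higher in 73 of 80 (75 over the list alone), median 1.85, limma camera adjusted p = 6.44e-23 and 0.15 with an estimated correlation. For Yap1 targets it was lower in 13 of 17 (13 over the list alone), median -2.15, limma camera adjusted p = 1.59e-06 and 0.131 with an estimated correlation. Probe sets numbered 1907 higher and 1694 lower (1079 and 956 by at least 2-fold), and across genes the effects at 1 h and 4 h correlated weakly (Pearson r = 0.168, genes not being independent replicates). With median centring the median of all probe sets was -0.10 and the split 1681 and 1973.

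Cold for 1 h raised ribosome assembly genes. The nucleolin gene NSR1 (2.50 ± 0.24), the large-subunit assembly gene RLP24 (2.47 ± 0.22), UTP13, of the small-subunit processome (2.37 ± 0.22), the RNA-binding protein gene VTS1 (2.35 ± 0.16) and the stress cell wall protein gene SPI1 (2.32 ± 0.20) rose most. NOP13 (2.30 ± 0.30), RLP7 (2.25 ± 0.26), NOG2 (2.15 ± 0.23), RPF2 (2.11 ± 0.28) and UTP14 (2.10 ± 0.19) followed. The histidine and lysine synthesis genes HIS4 (-1.86 ± 0.25) and LYS1 (-1.59 ± 0.22), ALD5 (-1.77 ± 0.23), ARO5 (-1.77 ± 0.25) and the meiotic helicase gene HFM1 (-1.55 ± 0.42) fell most. RTC2 (-1.52 ± 0.24), the sporulation septin gene SPR3 (-1.50 ± 0.34), YIG1 (-1.48 ± 0.40), the cyclin gene PCL5 (-1.39 ± 0.17) and YNCM0004C (-1.35 ± 0.40, uncertain for its probes) followed. Of the genes named throughout, TUB3 alone was called (-0.37 ± 0.13, limma adjusted p = 0.0498), a call that most alternatives ended. The others had TUB1 -0.09 ± 0.13, TUB2 -0.20 ± 0.10, IME1 -0.06 ± 0.29, IME2 -0.80 ± 0.42, NDT80 -0.50 ± 0.31, CLB1 0.32 ± 0.32, SPS1 0.39 ± 0.27, FLR1 -0.13 ± 0.36, PDR5 0.22 ± 0.19 and MAD2 -0.22 ± 0.16. In the control CLB1 (5.38) and SPS1 (5.15) lay below the filter level of 5.44, so a fall under cold could hardly be seen. With the DMSO arrays of the first set as control CLB1 turned to -0.88 and SPS1 to -1.80, and the prospore membrane and spore wall lists moved to -1.96 and -1.94. In all 924 probe sets were higher and 658 lower (263 and 83 by at least 2-fold), with 884 without replicate 1 of cold, 915 without replicate 2, and 2966 with the DMSO control. The control arrays differed more than most pairs (standard deviation 0.352), with array weights 883 probe sets were called, and on simulated data with this spread and 198 changed probe sets, 140 changes were recovered and 65 of 7724 unchanged probe sets were called.

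Ribosome biogenesis genes all rose at 1 h of cold: 45 of 45 rose, 45 over the list alone, median 1.43, limma camera adjusted p = 8.21e-33 and 0.138 with an estimated correlation, among them RRP8 (1.59 ± 0.15), EBP2 (1.83 ± 0.18), ROK1 (1.32 ± 0.14) and KRR1 (1.41 ± 0.15). Of recombination and synapsis genes 8 of 24 fell, 14 over the list alone, median -0.69, limma camera adjusted p = 1.29e-06 and 0.746 with an estimated correlation. Among them were MSH5 (-0.85 ± 0.18), SPO16 (-0.97 ± 0.23), SPO22 (-0.88 ± 0.23) and MEI4 (-1.26 ± 0.34). Of amino acid biosynthesis genes 10 of 24 fell, 16 over the list alone, median -0.65, limma camera adjusted p = 4.38e-07 and 0.746 with an estimated correlation. Its members included HIS1 (-1.06 ± 0.20) and LYS2 (-0.82 ± 0.19). Of meiotic division regulators 2 of 14 fell, 2 over the list alone, median -0.45, limma camera adjusted p = 0.0443 and 0.795 with an estimated correlation. Named members were MAM1 (-0.90 ± 0.16) and SGO1 (-0.86 ± 0.19). For meiotic entry regulators no member was called (median -0.44, limma camera adjusted p = 0.0476 and 0.795 with an estimated correlation). That call ended without any 1 of the 4 arrays, with median centring, values as deposited, no variance trend, the stricter dim filter, fry or the DMSO control. Of motors and associated genes 1 of 16 rose and 5 fell, 1 and 5 over the list alone, median -0.26, limma camera adjusted p = 0.0443 and 0.746 with an estimated correlation. The list held DYN1 (-0.87 ± 0.15), BIK1 (0.70 ± 0.15), SPC97 (-0.67 ± 0.15) and KAR3 (-0.96 ± 0.22). Glycolysis and glucose uptake genes were higher (3 of 16 rose, 3 over the list alone, median 0.31, limma camera adjusted p = 0.0448 and 0.795 with an estimated correlation): HXT2 (1.17 ± 0.22), PDC1 (0.95 ± 0.20) and ENO1 (0.60 ± 0.18, uncertain for its probes). Of sulfur and methionine genes 4 of 14 rose, 6 over the list alone, median 0.58, limma camera adjusted p = 0.0476 and 0.795 with an estimated correlation. Among them were MUP1 (1.87 ± 0.21), MET2 (0.91 ± 0.20), CYS3 (1.25 ± 0.29) and MET8 (1.30 ± 0.34). Without replicate 1 of cold 4 lists were called, and the motor list stood at -0.13 with no call. Without replicate 2 of the control 3 were called, with the motor list at -0.14 and the division list at -0.21, neither called. The division call also ended without replicate 2 of cold, with fry and with the stricter dim filter, and the motor call with that filter and with the DMSO control. The calls of the glycolysis and sulfur lists ended without replicate 1 of cold, without replicate 2 of the control and with no variance trend. That of the sulfur list also ended without replicate 1 of the control, with array weights, with fry and with the stricter dim filter. Ribosomal protein genes had no call (6 of 80 rose, 3 over the list alone, median 0.10, limma camera adjusted p = 0.361 and 0.832 with an estimated correlation) and gained one with median centring (adjusted p = 0.0136) and with values as deposited. The general stress, prospore membrane and spore wall lists gained calls with these scalings too. Median, mean and test differed in sign for tubulins (0.09, 0.03, down) and DNA damage (-0.12, 0.05, down).

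Cold for 4 h left sporulation genes far lower. The hexokinase gene HXK2 (3.27 ± 0.27), the proline permease gene PUT4 (3.23 ± 0.34), SIP18 (2.92 ± 0.32), SPG1 (2.89 ± 0.55) and NSR1 (2.81 ± 0.24) rose most. The cell wall mannoprotein gene SRL1 (2.72 ± 0.14), the malate synthase gene DAL7 (2.68 ± 0.22), the peroxisomal isocitrate dehydrogenase gene IDP3 (2.53 ± 0.36), the allantoicase gene DAL2 (2.44 ± 0.24) and RLP24 (2.38 ± 0.22) followed. YDL186W (-5.39 ± 0.39), YPR078C (-5.25 ± 0.34), PES4 (-5.03 ± 0.28), LDS2 (-5.00 ± 0.40) and RRT5 (-4.99 ± 0.25) fell most. SPR2 (-4.96 ± 0.33), YDR042C (-4.88 ± 0.30), SPR3 (-4.85 ± 0.34), the prospore protein gene SPO19 (-4.81 ± 0.39) and IRC18 (-4.59 ± 0.29) followed. TUB1 (-0.81 ± 0.13), TUB2 (-0.44 ± 0.10), TUB3 (-1.13 ± 0.13), IME2 (-1.59 ± 0.42), NDT80 (-2.06 ± 0.31), CLB1 (-2.64 ± 0.32) and SPS1 (-3.96 ± 0.27) fell. IME1 had -0.28 ± 0.29, FLR1 0.24 ± 0.36, PDR5 0.44 ± 0.19 and MAD2 -0.36 ± 0.16, none of them called. In all 1527 probe sets were higher and 1320 lower (420 and 433 by at least 2-fold). With values as deposited the split was 1144 and 1643, and with the DMSO control 4794 were called.

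The lists of spore formation were lower by the most at 4 h of cold. Of spore wall genes 15 of 19 fell, 16 over the list alone, median -3.11, limma camera adjusted p = 1.8e-14 and 0.0525 with an estimated correlation. Its members included CDA2 (-4.40 ± 0.23), DTR1 (-4.16 ± 0.25), GAS4 (-3.97 ± 0.24) and OSW1 (-3.91 ± 0.26). Of prospore membrane genes 16 of 16 fell, 16 over the list alone, median -2.69, limma camera adjusted p = 1.8e-14 and 0.076 with an estimated correlation. Named members were SPO20 (-4.26 ± 0.27) and SMK1 (-3.77 ± 0.28). Of meiotic division regulators 13 of 14 fell, 13 over the list alone, median -1.75, limma camera adjusted p = 1.78e-10 and 0.0763 with an estimated correlation. The list held MAM1 (-3.44 ± 0.16), CLB4 (-2.57 ± 0.21), CDC5 (-3.39 ± 0.30) and SGO1 (-1.97 ± 0.19). Of recombination and synapsis genes 23 of 24 fell, 24 over the list alone, median -1.24, limma camera adjusted p = 3.7e-09 and 0.123 with an estimated correlation. Among them were MSH5 (-1.98 ± 0.18), SPO16 (-2.03 ± 0.23), HOP2 (-1.26 ± 0.16) and SPO22 (-1.52 ± 0.23). Of motors and associated genes 1 of 16 rose and 10 fell, 1 and 13 over the list alone, median -0.60, limma camera adjusted p = 0.000168 and 0.0763 with an estimated correlation. Its members included STU2 (-2.69 ± 0.20), DYN1 (-1.25 ± 0.15), SPC42 (-1.50 ± 0.19) and KAR3 (-1.47 ± 0.22). Of spindle checkpoint genes 4 of 9 fell, 4 over the list alone, median -0.36, limma camera adjusted p = 0.0353 and 0.443 with an estimated correlation. Named members were MPS1 (-1.23 ± 0.30), BUB3 (-0.71 ± 0.18), ESP1 (-0.71 ± 0.26) and IPL1 (-0.75 ± 0.28), and the call ended without replicate 2 of cold. Heat shock chaperones were lower (9 of 17 fell, 10 over the list alone, median -0.76, limma camera adjusted p = 3.81e-05 and 0.0525 with an estimated correlation): AHA1 (-1.37 ± 0.12), SSA4 (-1.14 ± 0.13), SSA3 (-1.69 ± 0.21) and CPR6 (-0.89 ± 0.12). Of meiotic entry regulators 5 of 10 fell, 6 over the list alone, median -0.57, limma camera adjusted p = 0.0308 and 0.457 with an estimated correlation. The list held IME4 (-0.83 ± 0.20), RME1 (-0.66 ± 0.17) and MCK1 (-0.32 ± 0.10).

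Ribosome biogenesis genes stayed higher at 4 h of cold: 45 of 45 rose, 45 over the list alone, median 1.48, limma camera adjusted p = 7.36e-22 and 0.0763 with an estimated correlation, among them NIP7 (1.90 ± 0.16), GAR1 (2.17 ± 0.20), KRR1 (1.57 ± 0.15) and IMP4 (1.72 ± 0.16). Of glycolysis and glucose uptake genes 12 of 16 rose, 12 over the list alone, median 0.66, limma camera adjusted p = 0.00151 and 0.232 with an estimated correlation. Among them were PDC1 (1.93 ± 0.20), PDC5 (0.89 ± 0.16) and PFK2 (0.84 ± 0.15). Of cold-induced genes 5 of 11 rose and 0 fell, 6 and 1 over the list alone, median 0.34, limma camera adjusted p = 0.0371 and 0.105 with an estimated correlation. Its members included OPI3 (0.69 ± 0.11), BFR2 (1.26 ± 0.23) and TIR4 (0.70 ± 0.14). Of general stress genes 9 of 23 rose and 2 fell, 9 and 2 over the list alone, median 0.36, limma camera adjusted p = 0.0353 and 0.708 with an estimated correlation. Named members were HXK1 (1.29 ± 0.15), SPI1 (1.77 ± 0.20) and TSL1 (1.00 ± 0.15), and the call ended without replicate 1 of cold. Of TCA cycle and respiration genes 5 of 30 fell, 5 over the list alone, median -0.22, limma camera adjusted p = 0.0308 and 0.52 with an estimated correlation. The list held KGD2 (-0.71 ± 0.14), QCR2 (-0.67 ± 0.16), SDH4 (-0.55 ± 0.13) and KGD1 (-0.40 ± 0.11). That call ended with median centring (median -0.09), with values as deposited and without replicate 1 of the control. With the DMSO control the calls of the meiotic entry, cold-induced and respiration lists ended, and the ribosomal protein list (8 of 80 rose and 5 fell, 3 and 2 over the list alone, median -0.05, limma camera adjusted p = 0.826 and 0.967 with an estimated correlation) turned to 0.58. With median centring that list stood at 0.09 with no call.

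Between 1 h and 4 h of cold the difference was largest for spore genes. The effects on RRT5 (-5.25 ± 0.36), YDL186W (-5.16 ± 0.55) and YPR078C (-5.08 ± 0.49) moved down most, and those on ADH5 (2.67 ± 0.30), DIC1 (2.49 ± 0.31) and HIS4 (2.47 ± 0.35) moved up most. The difference was lower in 14 of 16 prospore membrane genes (14 over the list alone), median -2.59. It was lower in 14 of 19 spore wall (15) and 7 of 17 chaperone genes (11), medians -3.29 and -0.73. For these lists limma camera adjusted p was 5.57e-20, 5.57e-20 and 2.55e-08, and 0.0249, 0.0146 and 0.00945 with an estimated correlation. Probe sets numbered 223 higher and 394 lower (100 and 263 by at least 2-fold), against 110 and 472 with values as deposited. The count was 389 without replicate 1 of cold at 1 h, 407 without replicate 1 of cold at 4 h and 346 without replicate 2 of the 4 h control.

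**Figure D1:**
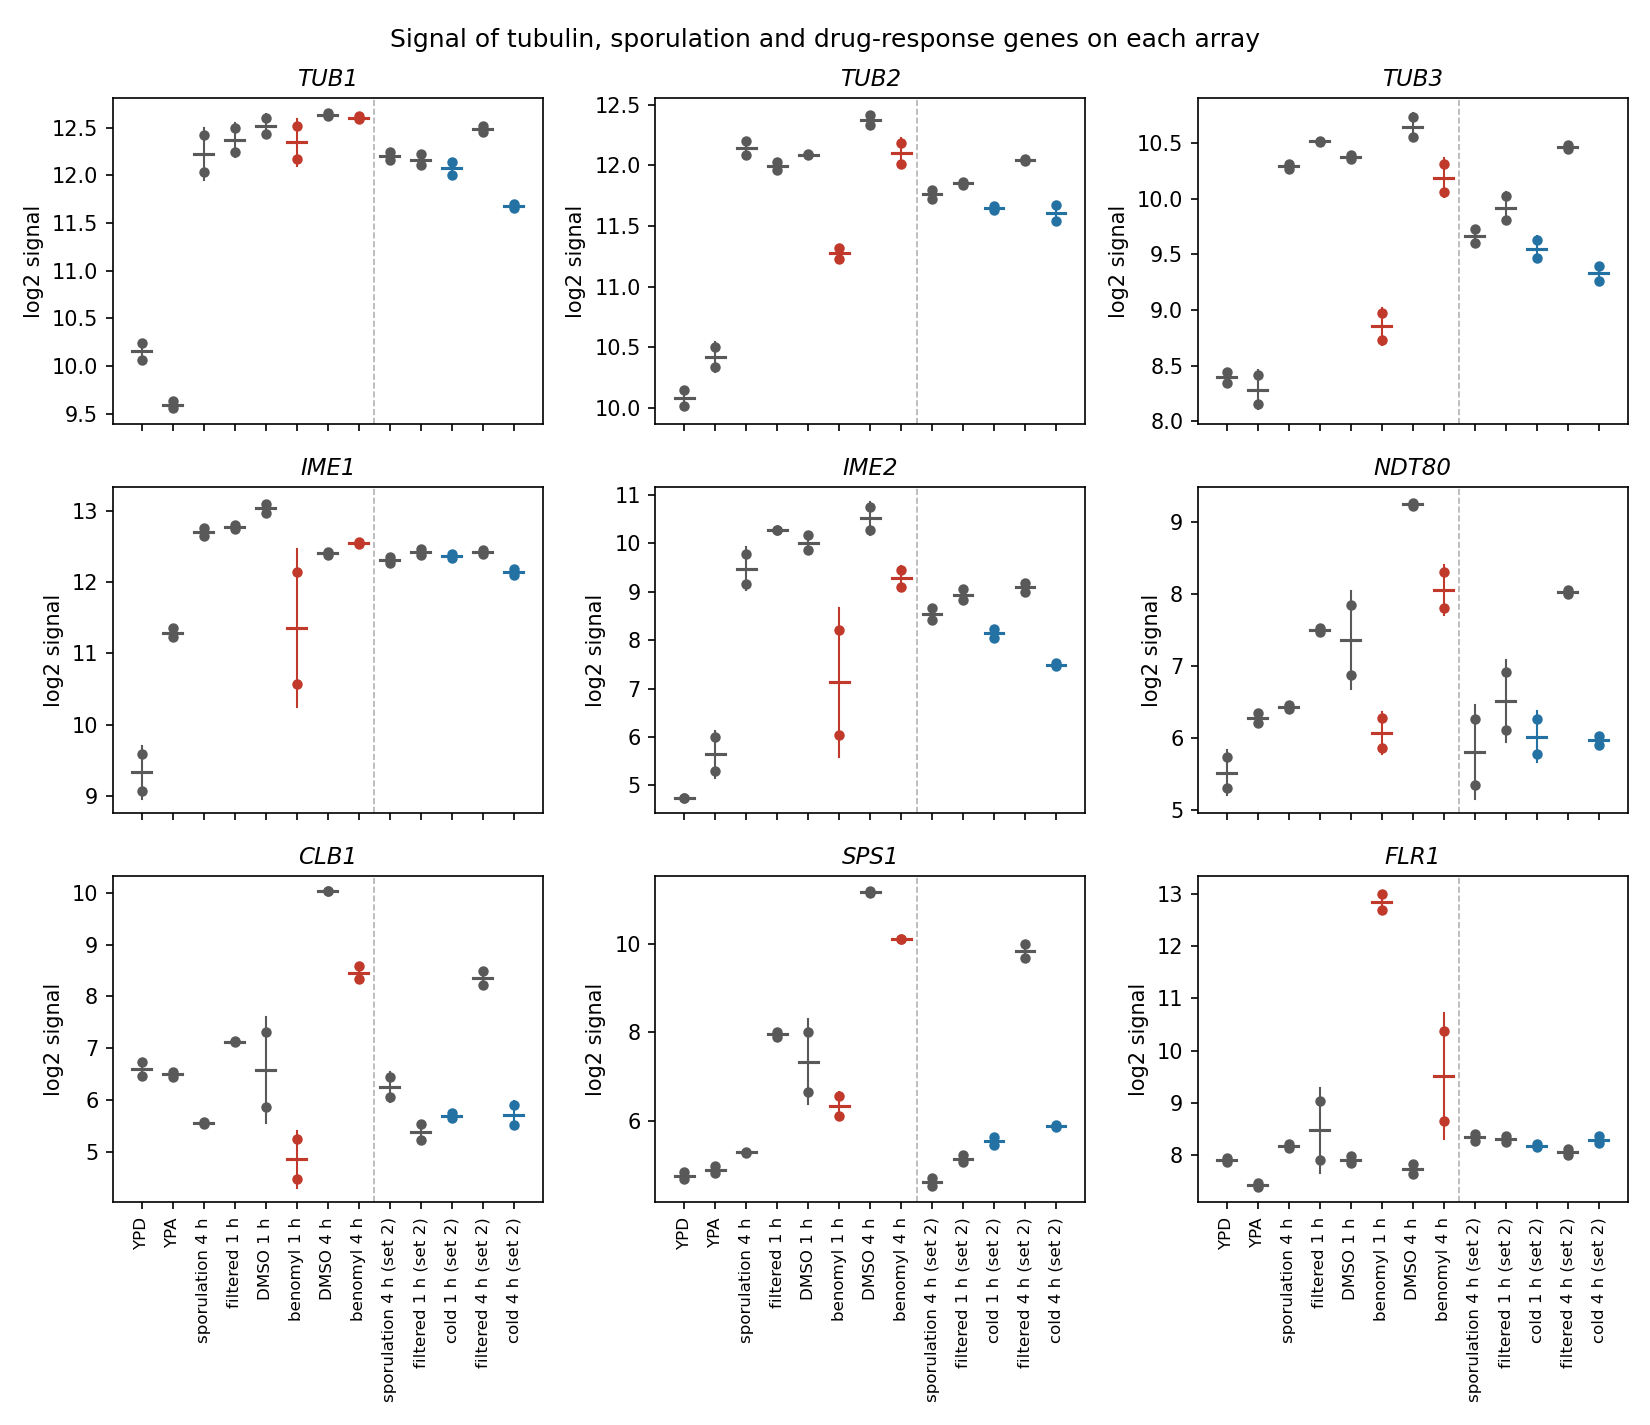
Log2 signal of 9 genes in the 13 groups. Points are both arrays, horizontal lines the mean and vertical bars the standard deviation (red benomyl, blue cold), and a dashed line separates the sets.

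At 1 h the effects of benomyl and cold differed for defence and ribosome genes. OYE3 (6.004 ± 0.36), YKL070W (5.97 ± 0.29) and FRM2 (5.71 ± 0.23) were higher under benomyl than under cold, and GLN1 (-4.24 ± 0.36), MEP2 (-4.14 ± 0.38) and PHO3 (-4.03 ± 0.39) lower. The benomyl effect was higher for 9 of 11 multidrug resistance genes (10 over the list alone), median 2.06, limma camera adjusted p = 4.24e-08 and 0.00811 with an estimated correlation. It was higher for 14 of 17 Yap1 targets (14 over the list alone), median 2.68, limma camera adjusted p = 1.48e-13 and 0.00811 with an estimated correlation. Ribosome biogenesis genes were lower in 42 of 45 (43 over the list alone), median -2.09, limma camera adjusted p = 4.72e-19 and 0.0963 with an estimated correlation. Probe sets numbered 1609 higher and 1718 lower (847 and 1008 by at least 2-fold), and 1665 were called with array weights. Across genes the effects of benomyl and cold at 1 h had Pearson r = 0.0849, with 0.123 without replicate 1 of benomyl, 0.0273 without its replicate 2 and 0.0498 without replicate 2 of the cold control.

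At 4 h benomyl and cold shared lower genes. JLP1 (4.88 ± 0.29), YLL056C (4.34 ± 0.43) and SPO19 (4.32 ± 0.55) were higher under benomyl than under cold, and HXK2 (-4.04 ± 0.38), FDH1 (-3.58 ± 0.63, uncertain for its probes) and DBP3 (-3.34 ± 0.51) lower. The benomyl effect was higher for 23 of 24 recombination and synapsis genes (24 over the list alone), median 1.65, limma camera adjusted p = 8.49e-10 and 0.178 with an estimated correlation. It was higher for 7 of 17 chaperone genes (8 over the list alone), median 0.92, limma camera adjusted p = 4.93e-06 and 0.0437 with an estimated correlation. Ribosome biogenesis genes were lower in 41 of 45 (43 over the list alone), median -1.50, limma camera adjusted p = 2.66e-21 and 0.178 with an estimated correlation. Probe sets numbered 1055 higher and 1056 lower (529 and 519 by at least 2-fold), against 826 and 1231 with median centring, and 3642 were called with array weights. Across genes, which are not independent replicates, the effects at 4 h had Pearson r = 0.404. Both effects fell for 450 genes, where 179.25 would be reached if they were independent, and both rose for 373, where 248.51 would be.

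**Figure D2:**
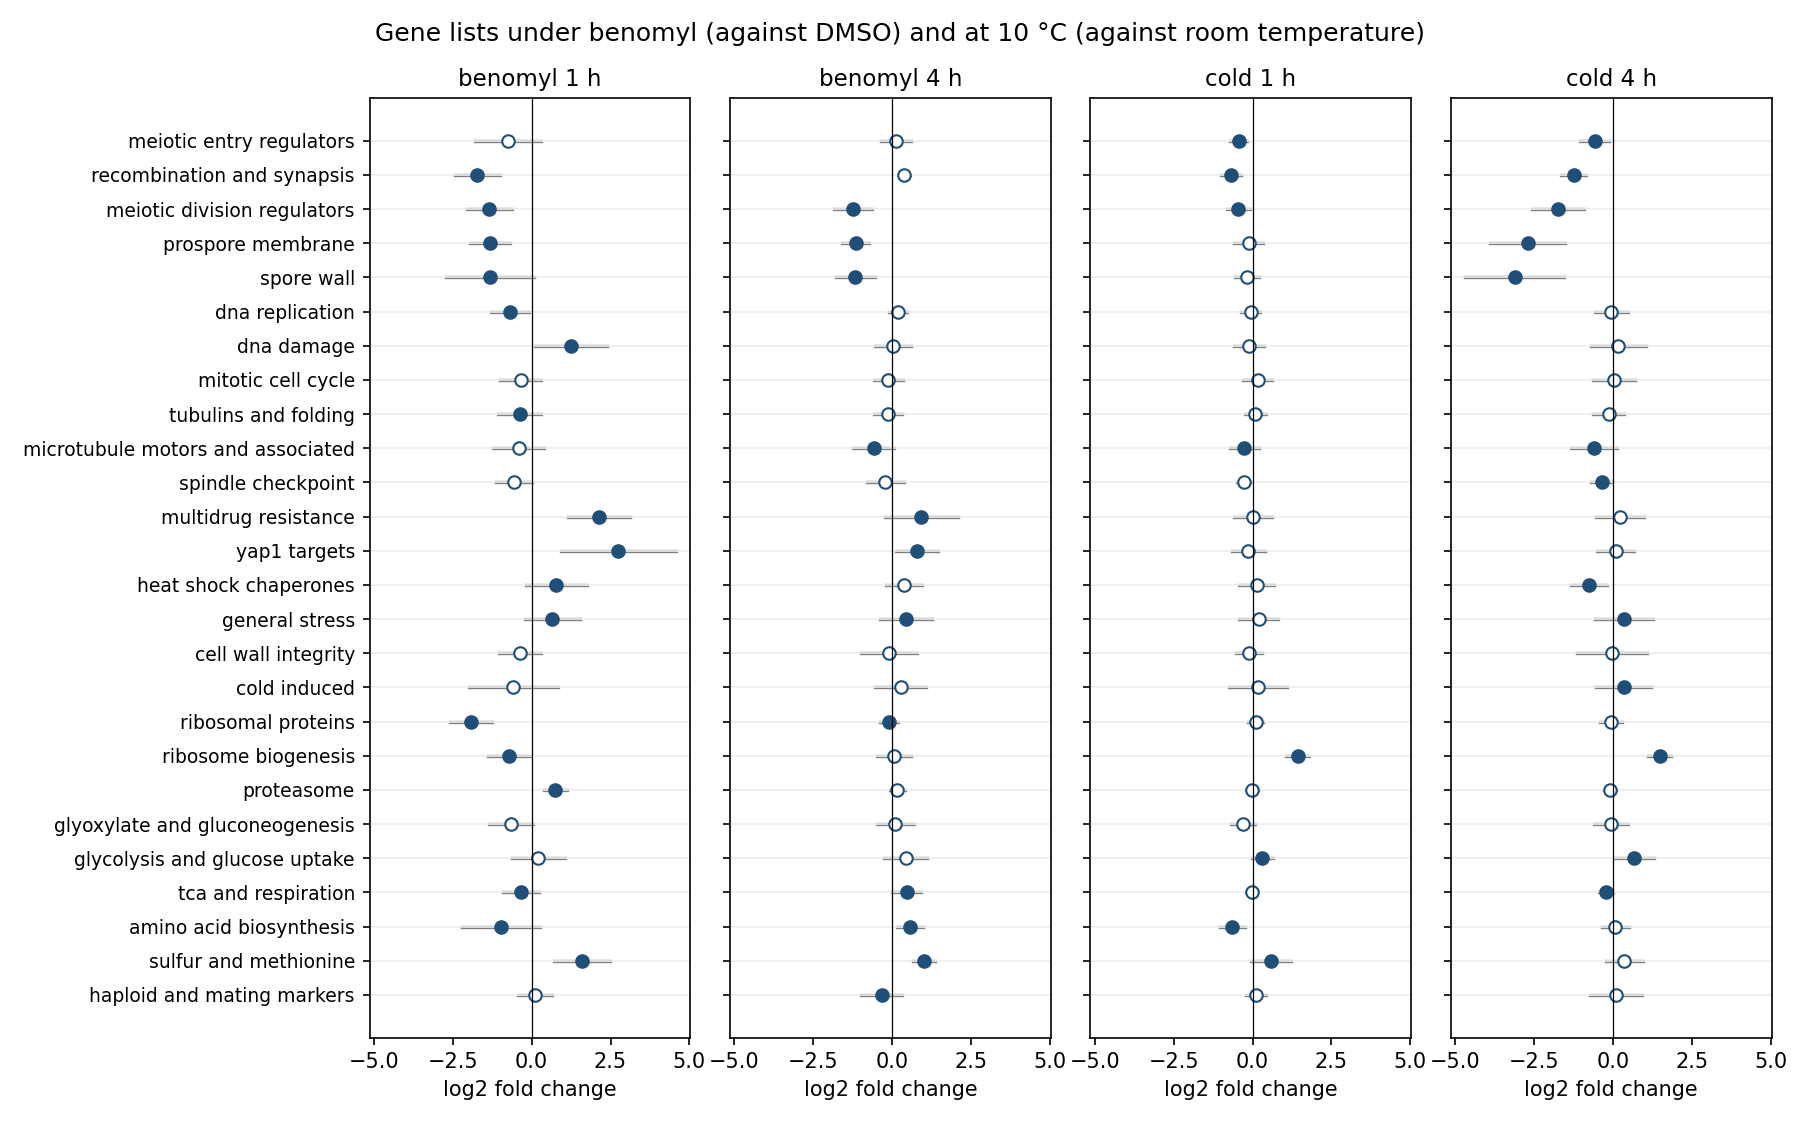
Median log2 fold change of 26 gene lists for benomyl and cold at 1 h and 4 h. Bars are the standard deviation across members, and filled dots mark a camera adjusted p under 0.05.

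Genes that rose at least 2-fold during the undrugged course were lower under both treatments at 4 h. Of 187 such genes chosen on the second set, 177 fell and 0 rose under benomyl at 4 h (median -1.43, limma camera p = 3.6e-58, and 0.00518 with an estimated correlation). At 1 h of benomyl 117 fell and 17 rose (median -0.81, limma camera p = 8.48e-09, and 0.256 with an estimated correlation). Of 584 genes chosen on the DMSO arrays, 365 fell and 18 rose at 4 h of cold (median -0.69, limma camera p = 6.7e-38, and 0.002 with an estimated correlation). At 1 h of cold 42 fell and 58 rose (median 0.01, limma camera p = 0.487, and 0.839 with an estimated correlation). In its control SPS1 (5.15) and CLB1 (5.38) lay below the filter level of 5.44, against 7.34 and 6.58 in DMSO at 1 h. Genes so low could hardly fall further, so the 1 h counts for cold cannot be compared with the others. Choice and test shared no array.

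**Figure D3:**
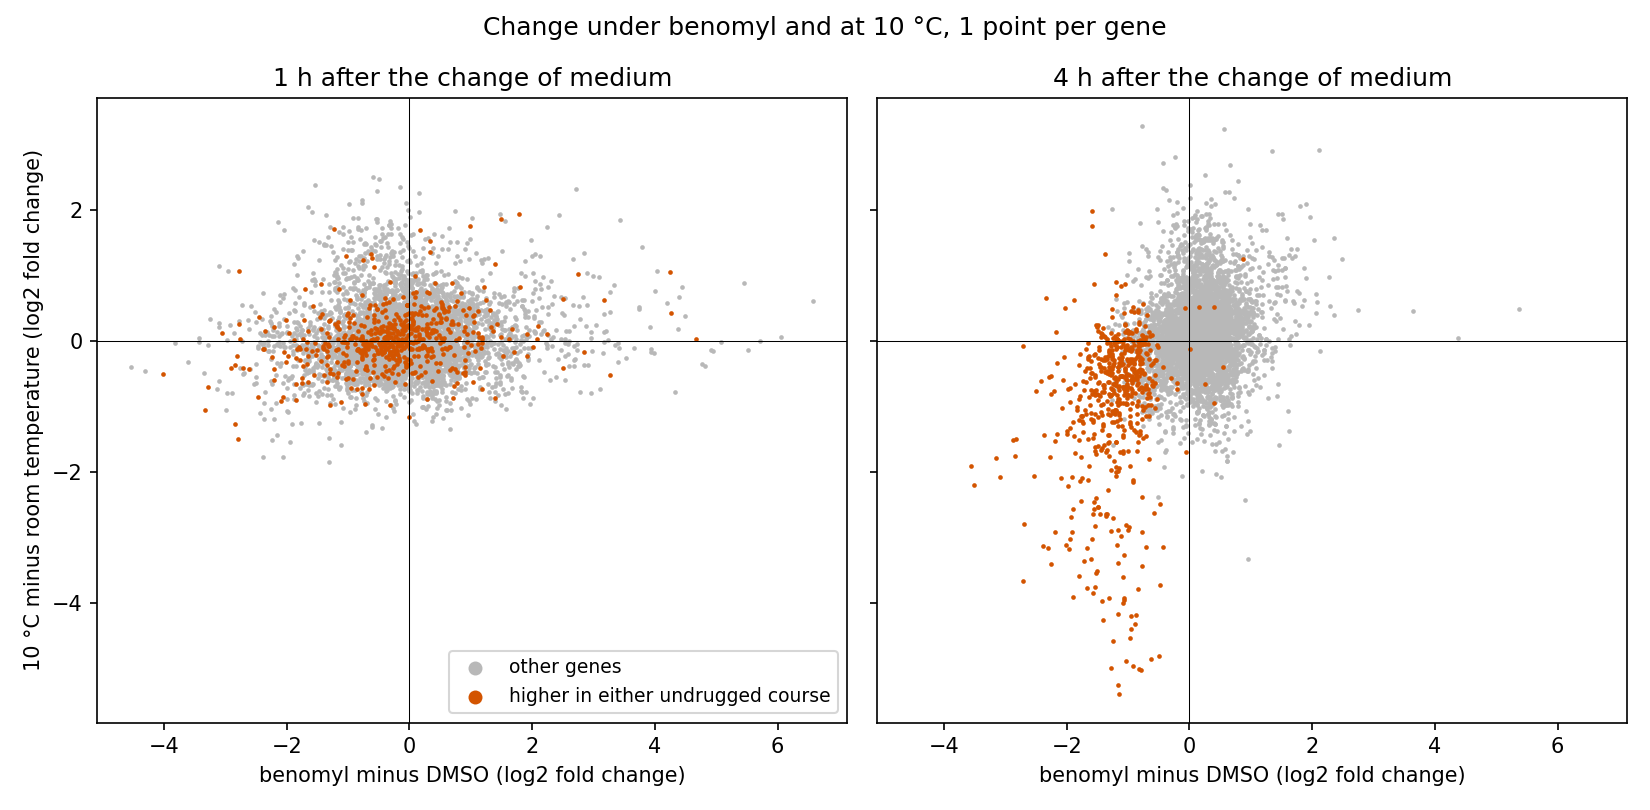
Log2 fold change under benomyl against that at 10 °C at 1 h and 4 h, for 5464 genes. Orange marks 586 genes higher by at least 2-fold in either course, chosen on arrays that include each effect's own controls, so part of their fall here is built in.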

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

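Array weights and the tests of a halted course, of 3' bias, of a stronger response, of compressed signal and of a different stage were chosen only after the result was seen, while values as deposited and the contrasts were chosen before. Lower course-induced genes under benomyl at 4 h may reflect a halted or delayed course. Across genes, which are not independent, the effect ran against the second set's course (Pearson r = -0.587). Course-induced genes were chosen in that course, so this r partly restates their fall and cannot single out a cause. Were quantile normalization the cause, the median should shrink with values as deposited, but it was -1.51 against -1.43. From 1 h to 4 h of benomyl mean SPS1 went from 6.3 to 10.1, CLB1 from 4.9 to 8.5 and NDT80 from 6.1 to 8.0. This argues against a full halt for them.

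The benomyl 1 h arrays differed more than any other pair. A 3' bias of the RNA could not be told from other causes (difference 0.116, against up to 0.200 in other pairs), and neither could a stronger response in one array (Pearson r = 0.0775 across genes). Noise of replicate 1 pushes that r below 0, so its small size does not speak against a stronger response in replicate 2. Compressed signal on one array was not borne out (slope -0.0112, against up to 0.0697 in size, in the second-set 1 h controls). With array weights 2019 probe sets were called in place of 4123, so small effects at 1 h could include false calls.

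The second-set 1 h control arrays stood apart as well. A 3' bias could not be told from other causes (0.161). The slope of their difference on mean level was the largest of all pairs (-0.0697, next 0.0213 in size), which compressed signal would give. It was not borne out as the whole cause, since the standard deviation was 0.352 once both arrays had the same distribution, against 0.343 as deposited. A different stage of sporulation was not borne out (Pearson r = -0.0213 across genes with the DMSO course).

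Effects were compared as contrasts. Probe sets whose effects differed numbered 3601 for benomyl 4 h against 1 h, 617 for cold 4 h against 1 h, and 3327 and 2111 for benomyl against cold at 1 h and 4 h, with 11, 8, 15 and 14 gene lists at the preset correlation, of which 0, 3, 2 and 1 held with an estimated correlation. For benomyl 4 h against 1 h the differences were TUB2 0.54, TUB3 1.06, IME1 1.83, IME2 1.64, FLR1 -3.14, PDR5 -1.69 and MAD2 -0.64. For cold 4 h against 1 h they were TUB1 -0.72, TUB3 -0.77, NDT80 -1.57, CLB1 -2.97 and SPS1 -4.35. Benomyl less cold at 1 h gave TUB2 -0.61, TUB3 -1.15, IME1 -1.62, IME2 -2.08, FLR1 5.05, PDR5 2.66 and MAD2 0.65. CLB1 had -2.05 and SPS1 -1.40. Both lay below the filter level in the cold 1 h control, so their differences from cold at 1 h cannot be read as treatment effects. Benomyl less cold at 4 h gave TUB1 0.78, TUB3 0.68, SPS1 2.90 and FLR1 1.54. Array weights ended the calls of TUB2 and MAD2 for benomyl 4 h against 1 h and at 1 h against cold, of CLB1 and SPS1 at 1 h against cold, and of NDT80 for cold 4 h against 1 h.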

How the results depend on the processing

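Each choice was changed alone, and the cause of a move was not tested unless stated. Counts and signs that moved are listed by setting, and list calls that ended stand beside their comparison. Ended calls of single genes are listed only in part: at least 1 alternative ended the call of 33 of 125 genes chosen by the naming rule for benomyl 1 h, 30 of 122 for benomyl 4 h, 48 of 85 for cold 1 h and 21 of 117 for cold 4 h. With array weights the called probe sets numbered 2019 for benomyl 1 h, 4121 for benomyl 4 h, 883 for cold 1 h, 1665 and 3642 for benomyl against cold at 1 h and 4 h, 288 for DMSO 1 h, 804 for filtration, 351 for the repeat course and 711 for the repeat set. With only the groups of the contrast they numbered 1208 for benomyl 1 h, 4062 for benomyl 4 h, 732 for cold 1 h, 1420 and 3536 for benomyl against cold at 1 h and 4 h, 507 for filtration, 324 for the repeat course and 279 for the repeat set. In the fit without the benomyl 1 h arrays and the second-set 1 h controls they numbered 3179 for benomyl against cold at 4 h, 213 for DMSO 1 h and 504 for filtration. By construction these fits change the pooled spread. With the replicate number as a block DMSO 1 h had 24 and the repeat set 1099, while residuals did not pair the samples by number. With the first set's DMSO arrays as control cold 1 h had 2966 and cold 4 h 4794, a change of set as well as of control. Signs turned with that control (cold 1 h: CDC21 0.38, cold 1 h: CLB1 -0.88, cold 1 h: RPS22B -0.0111, cold 1 h: SLT2 0.31, cold 1 h: SPS1 -1.80 and cold 1 h: YNCM0004C 0.34). The prospore membrane and spore wall lists at cold 1 h moved to -1.96 and -1.94. Signs turned at 4 h as well (cold 4 h: HTB2 0.74, cold 4 h: QCR2 0.13, cold 4 h: RPP1B 0.15 and the ribosomal protein list 0.58).

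With an estimated correlation 3 gene lists were called for benomyl 1 h, 0 for benomyl 4 h, 0 for cold 1 h and 0 for cold 4 h, and the course-induced genes at benomyl 1 h (median -0.81) lost their call. For cold 1 h 5 lists were called with no variance trend and 4 with the stricter dim filter. The course-induced genes at cold 1 h had -0.0240 with the 4-fold limit, which moved those at benomyl 1 h to -1.42 and at cold 4 h to -1.53, and -0.00918 with values as deposited. The benomyl and cold correlation at 4 h was 0.425 among genes called in either. Pseudocounts were not run, because the values were already log2.

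With each array left out in turn, the count ran from 3284 to 4469 for benomyl 1 h, 1516 to 2018 for benomyl 4 h, 2976 to 4252 for benomyl 4 h against 1 h, 884 to 1878 for cold 1 h, 1909 to 2130 for cold 4 h and 346 to 827 for cold 4 h against 1 h. For benomyl against cold it ran from 2701 to 4100 at 1 h and 1494 to 1745 at 4 h. It ran from 10 to 49 for DMSO 1 h, 2352 to 2765 for the DMSO course, 124 to 162 for filtration, 306 to 1044 for the repeat course, 548 to 2563 for the repeat set, 3694 to 3872 for sporulation 4 h and 1696 to 1932 for YPA against YPD. Lists called ran from 16 to 17 for benomyl 1 h, 11 to 13 for benomyl 4 h, 3 to 6 for cold 1 h and 12 to 14 for cold 4 h. The benomyl and cold correlation ran from 0.0273 to 0.123 at 1 h and 0.368 to 0.430 at 4 h. Medians of course-induced genes ran from -1.10 to -0.55 for benomyl 1 h, -1.56 to -1.31 for benomyl 4 h, -0.0535 to 0.0467 for cold 1 h and -0.74 to -0.66 for cold 4 h. The SPS1 difference (benomyl 4 h against 1 h: SPS1) ran from -0.73 without replicate 1 of DMSO at 1 h to 0.62 without replicate 2. The ribosomal protein list at benomyl 4 h ran from -0.24 without replicate 1 of benomyl to 0.0307 without replicate 2. These fits take the lone array to vary like the other groups. The number of arrays and, for dim probe sets, the signal over background limit the precision.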

Other observations

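The tests on genes called in neither course and on the change from acetate growth were written before their results were seen, and the gene lists tested below were chosen only after the values were seen. As a hypothesis, benomyl and cold may share lower genes at 4 h because both delay or halt the course. Among 2719 genes called in neither course the Pearson r across genes of both effects was 0.0559, against 0.404 over all genes and 0.505 among 2745 genes called in a course. These genes also varied less (standard deviation 0.394 against 0.799 for benomyl), and they were chosen partly on the control arrays of both effects, so the test could overstate the contrast. Samples treated at several ages would test it.

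A return toward the acetate growth state might lie behind the lower early sporulation genes at 1 h of benomyl, but the Pearson r across genes with the change from acetate to sporulation was -0.247, which could not tell.

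Some lists chosen after the values were seen were prompted by genes named above, so their p-values partly restate those genes. Of 42 tests (6 lists in 7 comparisons), 14 were called and 2 of these held with an estimated correlation, and without the named genes 13 and 1. The values below are without the named genes and serve as leads only. At 1 h of benomyl 18 of 22 ergosterol genes fell (median -1.16), 11 of 14 nitrogen catabolite genes (-1.42), 11 of 15 of fatty acid oxidation (-1.02) and 4 of 5 of fatty acid synthesis (-0.71). At 4 h of benomyl 11 ergosterol genes rose (0.58), as did 4 of fatty acid synthesis (0.92). Nitrogen catabolite genes rose in 9 of 14 at 4 h of cold (0.73) and fell in 12 during the DMSO course (-1.14), where 11 ergosterol (-0.54) and 4 fatty acid synthesis genes (-0.85) fell. In sporulation medium 7 of 12 phosphate genes fell (-0.70). In acetate against glucose, where scan day and medium cannot be told apart, 8 of 12 iron (0.97) and 4 of 12 phosphate genes (0.36) rose.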
